A study of Mus musculus with 6 samples.

How the data were processed

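RNA was sequenced from vagal jugular-nodose ganglia, the paired ganglia that hold the cell bodies of vagal sensory neurons, in 6 libraries. The sample titles put 3 libraries in a control group and 3 in a treated group. The protocol describes male C57BL/6J mice that carried subcutaneous osmotic pumps with PBS alone or with PBS and S961, a peptide antagonist of the insulin receptor, at 10 nmol per week for 2 weeks. The treatment label reads S961 for all 6 libraries, so that the control libraries came from PBS mice rests on the titles and the protocol. The source and tissue labels of all 6 libraries read spinal cord while the cell labels name the ganglia. The labels do not say whether replicates are separate animals, so every p-value here measures the spread between these samples. Libraries were made from about 6 ng of total RNA with a strand-specific kit for small inputs, from RNA with integrity numbers of 6.6 to 9.1 over the study's samples, and were read at 100 bp.

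Per the labels, the authors used bcl2fastq 2.20, STAR 2.7.7a, DESeq2 and edgeR with genome build mm10. The deposited values are counts, 1 file per library, with raw exonic reads per gene. The counting program, the annotation release and the strand setting are not given in the sources used here. The files name 32719 genes by Ensembl identifier, of which 32663 were matched to GENCODE M21, the source of all symbols and of all coordinates (GRCm38, the same build as mm10). A total of 56 symbols stood on more than 1 gene, 5101 genes had 0 counts in all libraries, and 0 genes were mitochondrially encoded. The summed gene counts exceeded the files' own number of reads that uniquely overlap a gene by 1.20% to 1.35%.

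Counts were fitted with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by the trimmed mean of M values (TMM), and treated was compared with control by a robust quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A positive log2 fold change means a higher level in the treated libraries, and its standard error (SE) was taken as its size divided by the square root of F. Levels are in CPM, which are counts scaled to the TMM-adjusted library size, with the SD over 3 libraries. The log2 levels of single libraries were computed with a prior count of 2. Two-sided exact permutation tests compared values between the groups, and with 3 libraries against 3 their smallest p is 0.1. The Fgf3 ratio of summed counts is given with a 95% exact binomial interval. Such intervals, and the limits set by low counts, cover counting error only. Correlations and principal components used genes above a log2 CPM of 2.

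Gene lists, the rule for naming genes and the tests were fixed before the data were examined. There were 46 lists for neuron types, signalling, metabolism, stress and the cell types that a dissected ganglion could hold, and lists with fewer than 5 tested genes were not tested as sets. Lists were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, again with camera and an estimated correlation, and with fry, with adjustment over the 38 tested lists. Camera compares a list with all other genes, and fry asks whether the genes of a list move on balance in 1 direction or, in its mixed form, in either. List members were also tested by edgeR p-values adjusted over the list alone, which is a weaker standard than adjustment over all genes. Named genes are Fgf3, the other tested genes of the FGF ligand list and list members chosen by p. The 15 genes with the smallest p at or above 1 CPM are named too. Some of the genes that this rule took from lists without a call are covered by their list's median only. The nodose, jugular and nerve injury lists were singled out for closer description after the results were seen, and Insr, Cckar, Vip, Ccnd1, Ucp1 and Adipoq were named after their values were seen.

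The alternatives fixed beforehand included other scalings (DESeq2 size factors, upper quartile and library size). They also included no filter, a filter at 5 CPM in 3 libraries, the replicate number as a block and each library left out in turn. Further ones were limma-voom with and without sample weights, the DESeq2 1.42.0 Wald test, and small-RNA and haemoglobin genes left out. The last were other thresholds (adjusted p under 0.1, or at least a 1.5-fold change) and the other list tests. Alternatives chosen after seeing the data were protein-coding genes only, the share of small RNA (small nuclear, small nucleolar and micro RNA) as a covariate, the mean level of the macrophage, neutrophil, fat cell and fibroblast lists as a covariate, removal of a length and GC trend, and a fit without robust shrinkage. The procedures were tested on simulated data with 200 of 16019 genes changed. There edgeR recovered 52% of 2-fold and 72% of 4-fold changes, and 7.46% of its 134 calls were false, whereas 26.2% of the 195 calls of DESeq2 were false. Those counts were drawn independently for each gene, without a library that stands apart, so these shares need not hold for the real data. Of 100 simulated unchanged lists, camera with its preset correlation called 0, in genes simulated without correlation between them. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.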

Results

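The 6 libraries held between 12898607 and 33522486 gene counts. The control replicates 1, 2 and 3 had 17810346, 25749857 and 14844384 counts, and the treated replicates 1, 2 and 3 had 33522486, 27856590 and 12898607. The mean was 19468196 ± 5638589 counts in controls and 24759228 ± 10655108 in treated libraries (SD, n = 3). Between 46.6% and 52.3% of reads overlapped a gene. Small RNA took 7.05%, 5.09% and 6.53% of the counts in the controls and 4.98%, 4.42% and 11.3% in the treated libraries. Treated replicate 3, the smallest library, stood apart from the rest. Its correlations with the other 5 libraries were 0.920 to 0.944 across genes, against 0.968 to 0.989 among those 5, where genes are not independent replicates. The first principal component held 58.0% of the variance of 12197 genes and placed this library at 53.6 and the others between -21.7 and 0.01.

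The comparison of treated with control ganglia asks how vagal sensory ganglia differ after infusion of S961 into the animal. Whether insulin signalling was blocked in the ganglia themselves was not measured here. Fgf3, a secreted fibroblast growth factor, is the gene the study's title names. Fgf3 counts were 1, 4 and 2 in the controls and 20, 77 and 13 in the treated libraries. Transcripts of nerve injury genes such as Atf3, Ecel1 and Sprr1a stood 9.65-fold, 39.5-fold and 42.8-fold higher in treated ganglia. Markers of jugular neurons were higher and markers of nodose neurons lower. In treated replicate 3, and to a lesser degree in treated replicate 2, transcripts of fat cells and neutrophils were also high. With edgeR 0 of 16019 genes passed at an adjusted p of 0.05, the smallest being 0.179, and 1068 genes had an unadjusted p under 0.05 (640 higher and 428 lower) where chance gives 801. DESeq2 called 96 genes, limma-voom 0, limma-voom with sample weights 8, and edgeR without its low-count filter 26, while edgeR called 7 without treated replicate 1 and 9 without treated replicate 3. All 3 treated libraries lay above all 3 controls for 1132 genes and below them for 1222, together 14.7% of those tested where chance gives 10%, and the smallest exact permutation p for 3 against 3 is 0.1.

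Fgf3 (ENSMUSG00000031074, chromosome 7, 144838083 to 144844436, plus strand, GRCm38) had 0.115 ± 0.0512 CPM in controls and 1.44 ± 1.10 CPM in treated ganglia (SD, n = 3). Its log2 fold change was 3.55 ± 0.80 (SE), with an edgeR adjusted p of 0.587 and an exact permutation p of 0.1. The summed counts of 7 in controls and 110 in treated libraries give a ratio of 12.2 relative to library size, with a 95% interval of 5.74 to 31.1. Treated replicate 2 held 77 of those counts, and without it the ratio was 5.95 with an interval of 2.59 to 15.9 and the log2 fold change was 2.68, while without treated replicate 1 the ratio was 18.1. Under the DESeq2 Wald test its log2 fold change was 3.61 at an adjusted p of 0.0359, and its adjusted p over the alternatives ran from 0.0359 to 0.995. The list named FGF ligands takes in the FGF family, not secreted ligands alone, and 14 of its 22 genes were tested. Of these 9 had a positive and 5 a negative log2 fold change, with a median of 0.36 that was 0.09 without treated replicate 3. Fgf3 alone rose when adjusted over the list alone, and the list as a set was not called (camera adjusted p = 0.264). The most abundant gene of that list, Fgf1, had 734 ± 16.7 CPM in controls and 518 ± 149 CPM in treated ganglia, a log2 fold change of -0.50 ± 0.21 that did not pass. Fgf11 was at 0.51 ± 0.24, Fgf7 at 0.62 ± 0.42, Fgf2 at 0.37 ± 0.23, Fgf22 at 0.53 ± 0.46, Fgf23 at 1.07 ± 1.18, Fgf14 at -0.37 ± 0.23 and Fgf18 at -0.28 ± 0.19. Without treated replicate 3 Fgf1 was at -0.28, Fgf7 at 0.0017, Fgf2 at 0.23, Fgf5 at 0.09, Fgf14 at -0.17 and Fgf23 at 0.17, while Fgf3 was at 3.72. Fgf11 was at 0.25 without treated replicate 2, and without control replicate 3 Fgf22 was at 0.26 and Fgf18 at -0.15. Fgf4 at 0.36 ± 0.59, Fgf5 at 0.56 ± 0.71, Fgf9 at 0.02 ± 0.27, Fgf12 at -0.06 ± 0.12 and Fgf13 at -0.01 ± 0.11 lay within their errors of 0, and each of these except Fgf12 changed sign with sample weights in limma-voom. Fgf21, which was not tested, had 8 counts over the controls and 2 over the treated libraries, and Fgf15 had 6 and 15.

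The gene with the smallest p was Sdc1, which encodes the cell-surface proteoglycan syndecan-1. It had 7.27 ± 0.798 CPM in controls and 30.7 ± 8.30 CPM in treated ganglia, a log2 fold change of 2.08 ± 0.22 (SE) at an edgeR adjusted p of 0.179. None of the 15 genes with the smallest p passed. Each had all 3 treated libraries on 1 side of all 3 controls, which a choice by p favours, so it adds no support. Those with higher values included Gpr151, an orphan receptor of sensory neurons, at 4.70 ± 0.61, the corepressor Nrip1 at 1.03 ± 0.14 and the cholesterol exporter Abca1 at 0.87 ± 0.13. The calcium channel subunit Cacna2d1, a target of gabapentin, stood at 0.73 ± 0.10, the metalloprotease Adam8 at 1.30 ± 0.20 and Slfn9 at 2.10 ± 0.34. The transcript Gm29374 at 5.05 ± 0.81 lies 672 bp downstream of Ecel1 on the same strand. Those with lower values were the muscle myosin light chain Myl1 at -1.01 ± 0.12, the imprinted gene Nnat at -0.86 ± 0.13 and the adhesion molecule Cntn5 at -0.96 ± 0.15. Sdc1 was also called by edgeR without treated replicate 1 and without treated replicate 3, the 1 gene shared by those 2 settings, with log2 fold changes of 2.27 and 1.90.

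Of the 16 genes of the nerve injury and regeneration list, 13 rose and 1 fell when adjusted over the list alone, while 0 passed over all genes. Atf3 (chromosome 1, 191170296 to 191218039), a transcription factor induced in injured sensory neurons, went from 6.02 ± 1.61 to 58.7 ± 20.1 CPM, a log2 fold change of 3.27 ± 0.33 (SE). The neuronal peptidase Ecel1 (chromosome 1, 87147655 to 87156521) went from 0.979 ± 0.398 to 38.3 ± 20.7 CPM, at 5.30 ± 0.56. The 1 member that fell was the neuropeptide Vip at -0.78 ± 0.23, which was named after its value was seen. Gadd45a, a growth arrest gene, rose by 1.07 ± 0.17, the neuropeptide galanin (Gal) by 1.01 ± 0.19 and the transcription factor Jun by 0.93 ± 0.18, each adjusted over the list alone. Sprr1a (chromosome 3, 92483952 to 92485895), a small proline-rich protein of regenerating axons and also a list member, went from 1.53 ± 1.00 to 65.0 ± 31.7 CPM, at 5.42 ± 0.66. The list median was 0.97, and camera called the list with its preset correlation (adjusted p = 1.5e-37) but not with an estimated correlation (adjusted p = 0.264 with an estimated correlation). Relative to the control mean, the mean log2 level of the list was 0.15, -0.06 and -0.09 in the controls and 0.89, 1.73 and 1.49 in the treated libraries (exact permutation p = 0.1). The 2 treated libraries with the higher values were also the 2 with the higher fat cell and neutrophil levels.

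**Figure D1:**
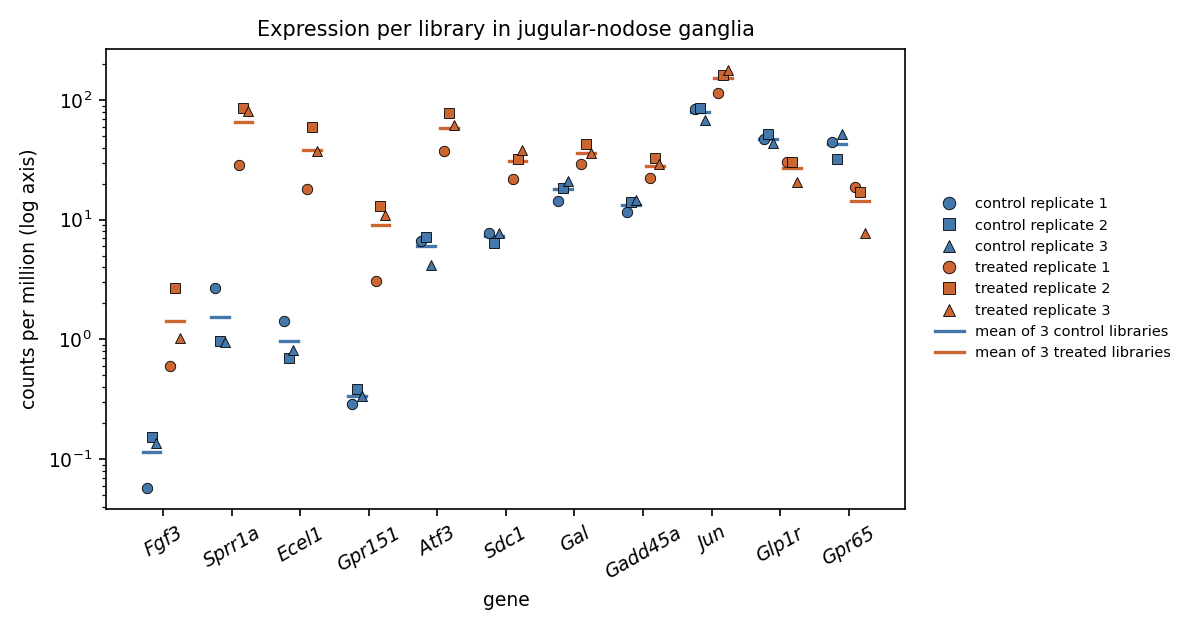
Levels of 11 genes in CPM on a log axis, with a point for each of the 3 control and 3 treated libraries and a line at each group mean. Fgf3, Atf3, Ecel1, Sprr1a, Gpr151, Sdc1, Gal, Gadd45a and Jun lie higher in all 3 treated libraries than in all 3 controls, and Glp1r and Gpr65 lie lower.

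Vagal sensory neurons of the nodose ganglion derive from placodes and serve the viscera, and those of the jugular ganglion derive from the neural crest. All 10 nodose markers had negative log2 fold changes with a median of -0.75, and 3 of them fell when adjusted over the list alone. Glp1r (chromosome 17, 30901817 to 30940791), the receptor of the gut hormone GLP-1, went from 47.6 ± 4.23 to 27.0 ± 5.44 CPM, a log2 fold change of -0.81 ± 0.16 (SE). Gpr65 (chromosome 12, 98268635 to 98276644), a proton-sensing receptor of neurons that innervate the gut, went from 42.9 ± 9.99 to 14.5 ± 5.85 CPM, at -1.55 ± 0.34. All 9 jugular markers had positive log2 fold changes with a median of 1.00, and 7 rose when adjusted over the list alone, among them the artemin receptor Gfra3 at 1.40 ± 0.30 and the transcription factor Runx1 at 0.75 ± 0.19. Camera called both lists with its preset correlation (adjusted p = 1.4e-13 for nodose and 1.2e-13 for jugular) and neither otherwise (adjusted p = 0.447 for each with an estimated correlation). The mean log2 level of the nodose list relative to the control mean was -0.53, -0.52 and -1.60 in the treated libraries, and that of the jugular list was 0.90, 0.44 and 1.51, so treated replicate 3 was the most extreme in both. Markers of sympathetic neurons and glomus cells, with which the nodose list shares 1 gene, were at -0.36, -0.57 and -1.39 in the treated libraries. Their controls were at 0.26, 0.14 and -0.40, so control replicate 3 lay below treated replicate 1 (exact permutation p = 0.2). The nodose controls were at 0.06, -0.02 and -0.04, without overlap (exact permutation p = 0.1). Without treated replicate 3 the nodose median was -0.45 and the jugular median 0.74. Pan-neuronal genes had a median of -0.04 (camera adjusted p = 0.760), with Rbfox3 at 0.28 ± 0.13, and without treated replicate 3 that list was called at a median of 0.11 (adjusted p = 0.0417).

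Hormone receptors of vagal afferents were lower as a set (median -0.10, camera adjusted p = 0.00339), a call that was lost with an estimated correlation (adjusted p = 0.447 with an estimated correlation) and without control replicate 2 (adjusted p = 0.0514, median -0.18), while without control replicate 3, treated replicate 2 or treated replicate 3 the median was -0.21, -0.24 or -0.22. Of its 13 tested genes, Glp1r fell when adjusted over the list alone. The neuropeptide Y receptor Npy1r was at 1.42 ± 0.39 and Cckar, the cholecystokinin receptor, at -0.10 ± 0.15. Among 21 genes for neuropeptides and their processing, 5 rose and 3 fell when adjusted over the list alone, with a median of 0.15 and no call (camera adjusted p = 0.386). Gal rose in this list too, and the secreted neurotrophic precursor Vgf rose by 0.63 ± 0.14. The neuropeptide median was 0.0099 without treated replicate 3 and 0.06 without control replicate 3, and without treated replicate 2 the list was called at a median of 0.22 (adjusted p = 0.0268). Ion channels of sensory neurons had a median of 0.01, whose sign differed between settings, and were not called (camera adjusted p = 0.760). Cacna2d1 rose when adjusted over that list alone, and the mechanically gated channel Piezo1 was at -0.39 ± 0.12.

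The insulin signalling list had a median of 0.08 (camera adjusted p = 0.0457, and adjusted p = 0.447 with an estimated correlation), and 0 of its 24 genes passed when adjusted over the list alone. The phosphatase Ptpn1 was at 0.52 ± 0.13, the PI3-kinase subunit Pik3r1 at 0.43 ± 0.11 and Insr, the insulin receptor, at -0.03 ± 0.09 (SE), with 73.7 ± 4.10 CPM in controls and 72.1 ± 3.94 CPM in treated ganglia. The call was lost without control replicate 1 (adjusted p = 0.162, median 0.07), control replicate 3 (0.138, median 0.04), treated replicate 1 (0.101, median 0.05) and treated replicate 2 (0.223, median 0.06). FoxO and fasting-responsive targets had a median of 0.14 (camera adjusted p = 0.00123, and adjusted p = 0.447 with an estimated correlation). Gadd45a alone rose of these 15 when adjusted over the list alone, with the repressor Bcl6 at 0.68 ± 0.20, and the call was lost without treated replicate 2 (adjusted p = 0.213, median 0.08). The mean log2 level of the FoxO list was 0.03, 0.43 and 0.36 in the treated libraries. In control replicate 2 it was 0.13, above treated replicate 1 (exact permutation p = 0.2). Treated replicates 2 and 3 had the higher fat cell and neutrophil levels. FGF receptors and ERK feedback genes had a median of 0.23 and were not called (camera adjusted p = 0.114), with the ERK inhibitor Spry2 at 0.43 ± 0.15 and the transcription factor Etv1 at -0.81 ± 0.23. That median was 0.04 without treated replicate 3 (adjusted p = 0.837) and 0.36 without control replicate 3. Glucocorticoid-responsive genes had a median of 0.60 (camera adjusted p = 1.7e-07, and adjusted p = 0.447 with an estimated correlation), and without treated replicate 2 it was 0.28 and without treated replicate 3 0.40. Of these 16 genes, the cell cycle inhibitor Cdkn1a rose by 0.92 ± 0.19 and the EGF receptor inhibitor Errfi1 by 0.48 ± 0.12, adjusted over the list alone. The mean log2 level of that list was 0.10, 1.00 and 0.89 in the treated libraries. In control replicate 1 it was 0.22, above treated replicate 1 (exact permutation p = 0.2). Treated replicates 2 and 3 also had the higher fat cell and neutrophil levels.

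Immediate early genes had a median of 0.41 (camera adjusted p = 0.00102, and adjusted p = 0.447 with an estimated correlation), which was 0.22 without treated replicate 3. The mean log2 level of that list was 0.05, 0.37 and 0.41 in the treated libraries and 0.10 in control replicate 2, so the higher values lay in treated replicates 2 and 3, which had the higher fat cell and neutrophil levels. Jun and Fosl2, both subunits of the AP-1 transcription factor, rose when adjusted over the list alone, Fosl2 by 0.82 ± 0.21 (SE). The circadian clock list had a median of 0.27 (camera adjusted p = 0.00221, and adjusted p = 0.447 with an estimated correlation), with Per1 at 0.65 ± 0.22 and Per2 at 0.62 ± 0.21. Per1 was at 0.36 without treated replicate 2 and Per2 at 0.40 without treated replicate 3. Its call was lost without treated replicate 2 (adjusted p = 0.0762, median 0.17), and its median was 0.16 without treated replicate 3. The mean log2 level of the clock list was 0.0012, 0.33 and 0.27 in the treated libraries, higher in the same 2 libraries with high fat cell and neutrophil levels. In control replicate 2 it was 0.04, above treated replicate 1 (exact permutation p = 0.2). Inflammatory cytokines and acute phase genes had a median of 1.13 (camera adjusted p = 1.3e-05, and adjusted p = 0.447 with an estimated correlation), which was 0.43 without treated replicate 3. The mean log2 level of this list was 0.51, 0.50 and 1.73 in the treated libraries, where that of macrophage markers was -0.17, 0.45 and 2.53 and that of neutrophil markers -0.93, 1.85 and 3.58. The acute phase gene Lcn2 was at 3.06 ± 0.95 and the adhesion molecule Vcam1 at 0.93 ± 0.34, and without treated replicate 3 they were at 1.87 and 0.57. Glycolysis genes had a median of -0.15, which was -0.03 without treated replicate 3 and -0.24 without treated replicate 1, and were not called (camera adjusted p = 0.386), although the liver-type phosphofructokinase Pfkl rose by 0.50 ± 0.10 and the glycolytic activator Pfkfb3 by 0.71 ± 0.17, adjusted over the list alone.

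Markers of cells other than neurons differed widely between libraries. Fat cell markers had a median of 3.39 (camera adjusted p = 1.9e-05, and adjusted p = 0.509 with an estimated correlation), with mean log2 levels of 0.80, -1.39 and 0.59 in the controls and -1.13, 2.05 and 4.56 in the treated libraries. Ucp1, the uncoupling protein of brown fat, had 40, 2 and 40 counts in the controls and 12, 253 and 986 in the treated libraries, and the fat hormone gene Adipoq had 312 counts in treated replicate 3. Adipsin (Cfd) was at 3.93 ± 1.74 and the lipase Lipe at 1.37 ± 0.62 (SE). Macrophage markers had a median of 1.35 (camera adjusted p = 4.4e-05, and adjusted p = 0.514 with an estimated correlation), with Adgre1 at 1.39 ± 0.55 and Tyrobp at 1.90 ± 0.94. Neutrophil markers had a median of 1.96 (camera adjusted p = 0.0121, and adjusted p = 0.529 with an estimated correlation), with Mpo at 2.41 ± 1.30 and S100a9 at 2.58 ± 1.45. Without treated replicate 3 the calls of all 3 lists were lost, at medians of 0.93 (adjusted p = 0.0933), 0.10 (adjusted p = 0.437) and 0.42 (adjusted p = 0.488). Without it Cfd was at 1.73, Lipe at 0.54, Adgre1 at 0.53, Tyrobp at 0.07, Mpo at 1.70 and S100a9 at 1.12. The neutrophil call was also lost without control replicate 2 (adjusted p = 0.167, median 1.61) and without treated replicate 2 (adjusted p = 0.0684, median 2.03), and without control replicate 3 its median was 3.34. Fibroblast markers had a median of 0.35 and were not called (camera adjusted p = 0.403), with Pi16 at 1.46 ± 0.95 and fibronectin (Fn1) at 0.64 ± 0.70. Without treated replicate 3 they were called in the other direction at a median of -0.46 (adjusted p = 1.3e-05), with Fn1 at -0.35 and Pi16 at 0.05, and they were called as higher without control replicate 3 (median 0.59, adjusted p = 0.0347) and without treated replicate 1 (median 0.68, adjusted p = 0.00149).

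Schwann cell markers had a median of 0.54 (camera adjusted p = 2.7e-07, and adjusted p = 0.447 with an estimated correlation), which ran from 0.34 without treated replicate 2 and 0.35 without control replicate 1 to 0.81 without control replicate 2. The myelin genes Pmp22 and Pllp were at 0.39 ± 0.15 and 0.90 ± 0.36 (SE), and 0 of these 14 genes passed when adjusted over the list alone. Without treated replicate 3 Pmp22 was at 0.25 and Pllp at 0.59. The mean log2 level of the Schwann list was 0.48 in control replicate 2, above 0.12 in treated replicate 1 (exact permutation p = 0.2). Satellite glia markers had a median of 0.17 and were not called (camera adjusted p = 0.136), with Glul at 0.42 ± 0.17. Their median was 0.07 without control replicate 1, and Glul was at 0.24 without treated replicate 3. Satellite glia markers were called without control replicate 2 (median 0.35, adjusted p = 0.00262) and without treated replicate 1 (median 0.27, adjusted p = 0.0219). Skeletal muscle markers had a median of -1.61 (camera adjusted p = 1.3e-08, and adjusted p = 0.447 with an estimated correlation), which was -0.95 without control replicate 3. Their mean log2 level was -1.33, 0.26 and 1.08 in the controls and -1.08, -2.28 and -0.55 in the treated libraries. Control replicate 1 thus lay below treated replicates 1 and 3, and the groups overlapped (exact permutation p = 0.3). Myl1 fell when adjusted over that list alone and Actn3 was at -1.82 ± 0.61. Markers of sympathetic neurons and glomus cells had a median of -0.73 (camera adjusted p = 1.8e-06, and adjusted p = 0.447 with an estimated correlation). Of these 8 genes the decarboxylase Ddc fell by 0.69 ± 0.14, adjusted over the list alone, and the noradrenaline-synthesizing enzyme Dbh was at -1.87 ± 0.65. Erythroid genes had a median of -1.03 (camera adjusted p = 0.000616, and adjusted p = 0.447 with an estimated correlation), with the haemoglobin genes Hbb-bs at -1.61 ± 0.56 and Hbb-bt at -1.25 ± 0.54. The erythroid median was -0.49 without control replicate 3 and -1.63 without treated replicate 3. The mean log2 level of that list was -0.58, -0.29 and 0.86 in the controls and -1.29, -1.43 and -0.16 in the treated libraries. The groups overlapped there as well (exact permutation p = 0.3). With 1 library left out Hbb-bs ran from -2.03 to -0.86 and Hbb-bt from -1.62 to -0.55. Endothelial markers had a median of 0.12 and mural markers 0.20, and neither was called (camera adjusted p = 0.621 and 0.106), though the mural median was 0.02 without control replicate 1 and mural markers were called without control replicate 2 (median 0.29, adjusted p = 0.0322) and without treated replicate 1 (median 0.50, adjusted p = 0.00365).

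**Figure D2:**
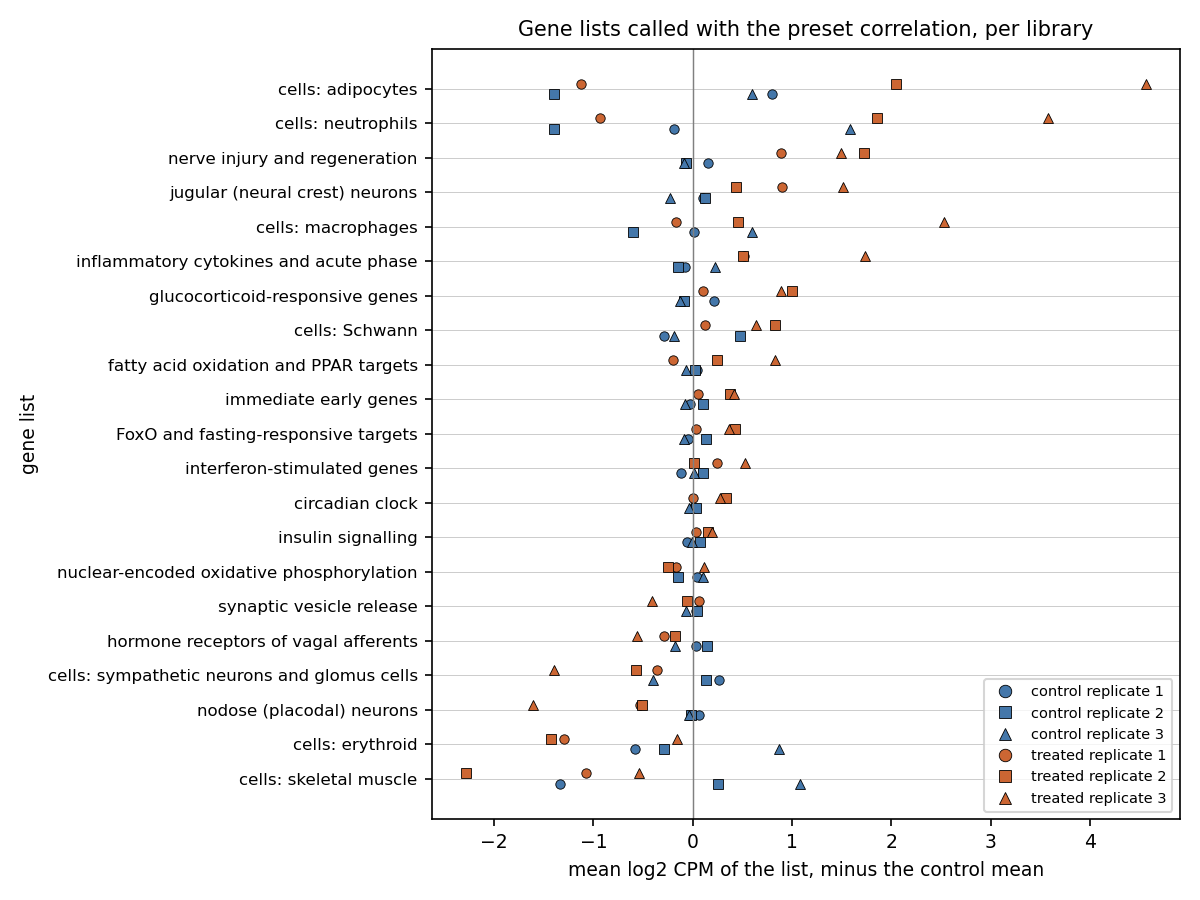
Mean log2 level of each of the 21 gene lists that camera called with its preset correlation, relative to the mean of the 3 control libraries, with a point for each library. The nerve injury and jugular lists lie higher and the nodose list lower in all 3 treated libraries than in all 3 controls, while treated replicate 3 holds the extreme values of the fat cell, neutrophil and macrophage lists.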

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

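Protein-coding genes only, the small-RNA covariate, the score of fat, immune and connective tissue cells as a covariate, the length and GC correction and the fit without robust shrinkage were chosen after seeing the data. The edgeR count of 0 genes (1068 at an unadjusted p under 0.05) stood at 0 under the other scalings, the filter at 5 CPM and limma-voom. It was also 0 with small-RNA and haemoglobin genes left out, protein-coding genes only, the length and GC correction and the fit without robust shrinkage. Both other thresholds gave 0 by construction, since the smallest adjusted p was 0.179 and a fold threshold only removes calls. The count was 26 with no filter, 1 with the replicate block, 8 with limma-voom and sample weights and 8 with the cell score covariate. It was 96 with DESeq2 and 101 with the small-RNA covariate, which shared 38 genes. With 1 library left out it ran from 0 to 9 (7 without treated replicate 1 and 9 without treated replicate 3). The labels do not say that replicate numbers pair the libraries. Across genes, deviations from the group mean correlated at 0.014, 0.56 and 0.49 between control and treated replicates 1, 2 and 3. For unlike numbers the correlations ran from -0.495 to 0.25, so a pairing was neither shown nor excluded. The count of 21 called lists was 0 with an estimated correlation (4 at an unadjusted p under 0.05), 0 with fry (7) and 0 with mixed fry, so the nodose (median -0.75), jugular (1.00) and nerve injury (0.97) lists lost their calls there and kept their medians by construction. Those 3 lists kept their calls in all 6 fits with 1 library left out and in 14 other settings. All of these used camera at the preset correlation of 0.01, so they share that assumption and are not independent support. The estimated correlations were 0.81 for nodose, 0.71 for jugular and 0.44 for nerve injury genes. Fgf3 had a log2 fold change of 3.61 and passed with DESeq2, ran from 2.68 to 3.93 with 1 library left out, and was removed by the filter at 5 CPM. With sample weights the log2 fold change was -0.43 for Fgf4, -0.10 for Fgf5, -0.090 for Fgf9, 0.019 for Fgf13 and -0.11 for Fn1, and the list median was 0.067 for pan-neuronal genes, -0.027 for neuropeptides, -0.035 for FGF ligands, 0.017 for cholesterol, -0.16 for ribosomal proteins, -0.21 for fibroblasts and -0.066 for endothelium, each the reverse of its sign with edgeR. Fgf13 was also 0.0062 with library size only, 0.0050 with the length and GC correction and 0.015 with the small-RNA covariate, under which fibroblasts were at -0.058. With the cell score covariate Fgf13 was 0.088 and Fn1 -0.24, and list medians were 0.063 for pan-neuronal genes, 0.033 for cholesterol, -0.14 for ribosomal proteins, -0.49 for fibroblasts, -0.064 for endothelium and -0.035 for neutrophils, the last and fibroblasts being part of that score. At 5 CPM the FGF ligands were at -0.030 and histones at 0.0070. The ion channel median was -0.0062 with the upper quartile, -0.0032 with no filter, -0.013 with the block, -0.020 with limma-voom and -0.012 with the length and GC correction. With 1 library left out, signs turned within -0.15 to 0.74 for Fgf4, -0.20 to 0.21 for Fgf9, -0.19 to 0.0025 for Fgf12, -0.12 to 0.083 for Fgf13, -0.22 to 0.012 for Cckar and -0.35 to 0.98 for Fn1. List medians did so within -0.13 to 0.11 for pan-neuronal genes, -0.0047 to 0.27 for fatty acid oxidation, -0.15 to 0.057 for cholesterol, -0.21 to 0.29 for ribosomal proteins, -0.074 to 0.15 for ion channels, -0.46 to 0.68 for fibroblasts and -0.073 to 0.28 for endothelium. The cause was not tested for any of these, beyond the fewer libraries or genes that a setting holds. Of 82 genes named with a log2 fold change, 63 were tested under every setting, 75 kept their direction wherever they were tested and 30 passed under at least 1, while 34 moved by over 1.5 times when some library was left out. Depth limits Fgf3, with 1 to 4 counts per control library.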

Other observations

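The tests of treated replicate 3, small-RNA share, pan-neuronal markers, marker heterogeneity, Fgf3 counting error, Fgf3 neighbours, library order and other splits were chosen after the results were seen, and that of the non-neuronal cell score was written before its result, but after the levels of those cell markers had been seen. Interferon-stimulated genes had a median log2 fold change of 0.29 (camera adjusted p = 0.0108, and adjusted p = 0.514 with an estimated correlation), with the antiviral gene Ifit3 at 0.56 ± 0.17 (SE) and Oas1a at -0.66 ± 0.24. The call was lost without control replicate 1 (adjusted p = 0.0883, median 0.25), treated replicate 1 (0.102, median 0.34) and treated replicate 3 (0.0996, median 0.17), and the median was 0.47 without treated replicate 2. Nuclear genes of oxidative phosphorylation had a median of -0.10 (camera adjusted p = 0.0108, and adjusted p = 0.514 with an estimated correlation), with the complex I subunit Ndufa9 at -0.21 ± 0.08. That call was lost without control replicate 3 (adjusted p = 0.0714, median -0.09), treated replicate 1 (0.0894, median -0.10) and treated replicate 2 (0.238, median -0.05), and the median was -0.16 without control replicate 2 and -0.19 without treated replicate 3. Synaptic vesicle genes had a median of -0.16 (camera adjusted p = 0.0108, and adjusted p = 0.650 with an estimated correlation), with the fusion protein Snap25 at -0.39 ± 0.18 and the vesicle protein Sv2b at 0.34 ± 0.11. The synaptic call was lost without control replicate 2 (adjusted p = 0.0625, median -0.15) and treated replicate 3 (0.837, median -0.04), and the median was -0.27 without treated replicate 1. Snap25 was at -0.21 without treated replicate 3, and Sv2b ran from 0.21 to 0.40 with 1 library left out. Fatty acid oxidation genes had a median of 0.18 (camera adjusted p = 0.0358, and adjusted p = 0.555 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.0517, median 0.22), control replicate 3 (0.128, median 0.16), treated replicate 2 (0.0601, median 0.27) and treated replicate 3 (0.837, median -0.0047). Its mean log2 level was -0.20, 0.24 and 0.83 in the treated libraries, where that of fat cell markers was -1.13, 2.05 and 4.56. In none of these 4 lists did a gene pass when adjusted over the list alone.

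Lists that were not called were other growth factors (median 0.14, camera adjusted p = 0.475), with Wnt5a at 0.89 ± 0.21 and Tgfa at 0.83 ± 0.26 (SE), cholesterol synthesis (-0.06, 0.243), cytosolic ribosomal proteins (0.15, 0.136), the unfolded protein response (0.06, 0.561), heat shock (-0.10, 0.269), the cell cycle (0.25, 0.374) and histones (-0.14, 0.386). Ribosomal protein genes were called as higher without control replicate 3 (median 0.27, adjusted p = 0.000819), treated replicate 1 (0.265, 0.0103) and treated replicate 2 (0.29, 0.000657), and as lower without treated replicate 3 (-0.21, 1.3e-05). Cholesterol genes were called as lower without control replicate 1 (-0.07, 0.0489) and treated replicate 1 (-0.15, 0.0135), cell cycle genes as higher without treated replicate 1 (0.41, 0.0499), and histones as lower without treated replicate 3 (-0.21, 0.0451). With 1 library left out, the median of other growth factors was 0.04 without treated replicate 3 and 0.05 without control replicate 3, and that of the unfolded protein response was 0.0059 without treated replicate 2 and 0.11 without control replicate 1. That of heat shock was -0.17 without treated replicate 1 and -0.06 without treated replicate 3, that of the cell cycle 0.09 without control replicate 1, and that of histones -0.04 without control replicate 1. Kit, from the list of mast cells, rose by 0.62 ± 0.20 and E-cadherin (Cdh1), from the list of secretory epithelium, by 0.84 ± 0.18. Each was adjusted over the list alone, where 2 genes of each list were tested. Kit and Cdh1 averaged 46.5 and 128 CPM, against 0.614 for Tpsb2 and 19.3 for Amy1, the other tested genes of those lists. Which cells made Kit and Cdh1 was not determined. Lists too small to test as sets had medians of 0.52 for lymphocytes, 0.32 for mast cells, 0.02 for thyroid, 0.40 for secretory epithelium, 0.51 for cartilage and bone, 0.12 for spinal cord and brain, and -0.07 for sex-linked genes, and 0 mitochondrially encoded genes were counted. The oligodendrocyte gene Mog had 2 counts in treated replicate 1 and 0 in the other 5 libraries. Of the same list, Opalin had 5 counts in treated replicate 1, 16 in treated replicate 3 and 0 in the rest, and Mobp had 0 to 5 per library.

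Of the 16 nerve injury genes, 13 were higher in all 3 treated libraries than in all 3 controls, and of these Gal, Nts, Jun and Gadd45a also stand in other lists. The 3 others had negative log2 fold changes, and of these only Vip was lower in all 3 treated libraries than in all 3 controls. Treated replicate 3 alone cannot account for the higher level of the list, since without it the median was 0.91 against 0.97 in all 6 libraries. Nor can RNA of immune, fat and connective tissue cells as the whole cause, since with a score of those cells as a covariate the median was 0.86, with 13 members above 2 SE. With the share of small RNA as a covariate it was 0.95. Only 1 of the 10 splits of the 6 libraries, the real one, gave a median as far from 0 as 0.97 (the highest other was 0.61), and 10 splits are too few for a share under 0.05, so an injury-like response to the S961 infusion, or to handling that differed between the groups, may underlie it and neither was tested.

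Nodose markers were lower and jugular markers higher in treated ganglia. Markers of sympathetic neurons and glomus cells had a median of -0.73, but their mean level in control replicate 3 lay below that in treated replicate 1. A loss of neurons in general would lower all neuronal markers, yet the pan-neuronal median was -0.042, and the treated-minus-control difference in mean log2 level was higher for pan-neuronal than for nodose genes by 0.87 with an SE of 0.27, while the jugular median was 1.00. Without treated replicate 3 the nodose median was -0.45 and the jugular median 0.74. The 10 nodose markers fell by unequal amounts, with Cckar at -0.10 ± 0.15 (SE) and Gpr65 at -1.55 ± 0.34. Their heterogeneity statistic Q was 26.3 on 9 degrees of freedom (99% point 21.7). One common drop in the share of nodose neurons would lower them alike only if nodose neurons alone made each marker. That was not measured, so Q cannot exclude such a drop. A smaller share of nodose neurons, or of some of their subtypes, in the dissected samples could underlie the pattern. So could different shares of jugular tissue or of adjoining tissue with sympathetic or glomus cells, or regulation within neurons after S961. These were not told apart by a test.

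Fgf3 was higher in all 3 treated libraries. Counting error alone would leave a ratio near 1, but the lower 95% bound of the ratio of summed counts was 5.74, or 2.59 without treated replicate 2. Reads that run over from a neighbour would raise that neighbour too. Among 5 tested genes within 100 kb the highest log2 fold change was 0.56 (Ccnd1), with Fgf4 at 0.36 ± 0.59 (SE) against 3.55 ± 0.80 for Fgf3. None of those 5 lies upstream of Fgf3 on its own strand, so the values cannot decide on run-over along that strand. Fgf3 may be part of the same response as the nerve injury genes, and both order the treated libraries alike, but this decides nothing, since 3 libraries fall in a given order with a chance of 0.167. A response of Fgf3 to S961 stays open as well.

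For the count of 0 genes called by edgeR (1068 at an unadjusted p under 0.05, 96 called by DESeq2), all 10 splits of the libraries give at least as many by construction, so this count tests nothing. At an unadjusted p under 0.05 the highest other split gave 1661 genes, and it was also the highest by adjusted p with 124. That split set control replicates 1 and 3 and treated replicate 3 against the rest, which are the 3 libraries with the highest shares of small RNA, so the samples have a structure that crosses the groups. For the 21 lists called with the preset correlation, 4 of the 10 splits gave as many, with 22 as the highest other. With 10 splits no share can be under 0.05.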
